A study of Mus musculus with 6 samples.

How the data were processed

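Total RNA of whole liver, extracted with Trizol, was sequenced from C57BL/6 mice after library preparation with the NEBNext Ultra II Directional kit, per the labels' protocols. The 6 libraries fall into an aging group and a group of aging mice treated with BPTES, 3 in each, by the treatment given in the labels. The labels do not say what the aging group was injected with, nor that each library came from its own animal, so p-values measure the spread between these libraries. The labels give no sequencing batch or date.

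The deposited table holds raw read counts per gene for 15848 protein-coding genes, per the file headers. Per the submitters' processing notes, cutadapt 1.9.3 and HISAT2 2.0.4 were used with the mouse build mm10; the human build hg19 is also listed there, but the gene identifiers are mouse ones. The read counter, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping, antisense and near-identical genes cannot be assigned with certainty. The table also holds 6 columns of the authors' normalized log2 values under the same names, which were not used here. Genes absent from the table were not analysed here. Coordinates come from GENCODE M21, on the same build, by Ensembl identifier, which matched 15719 genes; they are 1-based and span the whole gene, exons and introns. Gene length is the union of its exons.

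The counts summed to 14803504 to 28779222 per library, so 1 read was worth 0.0347 to 0.0676 CPM. Intervals of read ratios (95%) cover counting error only. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 12388 tested genes and 3460 below the filter. The filter was applied anew whenever a library was left out. The tested members of a list can differ there, and its median can shift for that reason too. Counts were scaled with TMM and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are counts scaled to a common library size with the TMM factors. Log2 fold changes are BPTES against aging; the SE is the fold change divided by the root of the F statistic. Gene lists were tested with camera on log2 CPM (prior count 1, preset correlation 0.01) where at least 5 members were tested; camera compares a list with the other genes. In 5 lists (adipose, intestine, muscle, pancreas and sex chromosome genes) fewer were tested. The direction within a list was checked with fry. Marker scores are means over 16 M2 genes, without Arg1, and 15 M1 genes of log2 CPM centred over the 6 libraries, and were tested with an exact two-sided permutation test. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.

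The groups, tests, lists, named-gene rule and most alternatives were fixed before the data were examined. The rule names genes of glutamine metabolism and macrophages whatever their values, among them Gls2, Glul, Mrc1, Cd163, Arg1, Clec4f, Adgre1, Nos2, Tnf, Il1b and Il6. It adds the 10 largest changes in each direction among genes past the threshold, predicted models and pseudogenes left out, whose groups did not overlap and whose mean was at least 1 CPM, and the 4 members with the smallest p of each list past the threshold. Genes outside the rule are said to be named after their values were seen.

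The procedure was tested on simulated data with the means, spread and library sizes of these libraries. Of 98 tested genes changed 2-fold 5.10% were recovered, and of 94 changed 4-fold 48.9%; 4 of 11948 unchanged genes and 0 of 40 unchanged lists were called. With the spread estimated over all 6 libraries, genes that change by 2-fold are therefore mostly not detectable. Every simulated library received that spread, which includes the distance of aging replicate 1 from its group. Without that library the biological coefficient of variation was 0.256, against 0.388 with all 6. Recovery at the smaller spread was not simulated. The genes were simulated independently of each other, so the 0 of 40 lists does not show how camera behaves on lists whose genes move together. Alternatives were DESeq2's size factors for scaling, no filter, a filter of a mean of at least 5 CPM, a prior count of 0.1, the DESeq2 Wald test, limma-voom, a block for the replicate number, each library left out in turn, a fold threshold, an adjusted p threshold of 0.1, an estimated correlation between genes, list members below the filter added back, Arg1 in the M2 score and genes scaled to unit SD. Added after the data were seen were limma-voom with a weight per library, removal of a length trend (loess, span 0.3), both replicates numbered 1 left out, robust hyperparameters, the male-biased list without Mup genes and camera over KEGG pathways with at least 10 tested genes.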

Results

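Liver RNA of C57BL/6 mice was sequenced to compare aging animals with aging animals given BPTES, a small-molecule inhibitor of glutamine metabolism. The animals were 12 months old at the start, and BPTES was injected intraperitoneally at 12.5 mg/kg, 3 times per week, over 2 months. Each group held 3 libraries, called here aging replicates 1 to 3 and BPTES replicates 1 to 3. The counts summed to 21910181, 28779222 and 27834073 in the aging libraries and to 14803504, 22864434 and 24336308 in the BPTES libraries. The series title places the experiment in the study of glutamine and M2 polarization of macrophages in the aging liver, so the comparison addressed which liver genes differ between animals with and without BPTES. All 6 libraries carried Y-linked transcripts: Ddx3y lay at 142 ± 8.97 CPM in the aging group and 126 ± 11.5 CPM in the BPTES group (SD, n = 3 each), with no difference past the threshold (adjusted p = 0.732, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

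With BPTES, the list of genes that are normally higher in male mouse liver rose, with a median log2 fold change of 2.01, as did chaperone genes of the endoplasmic reticulum and of the cytosol, with medians of 1.10 and 0.91 (n = 3 libraries per group). Lists of female-biased liver genes, Kupffer cells, neutrophils and the acute-phase response passed downward with camera's preset correlation, with medians of -3.89, -1.35, -3.25 and -1.24. These 4 calls were lost with an estimated correlation (camera adjusted p = 0.0612, 0.0537, 0.0881 and 0.102). Fry, which checks the direction within a list, gave adjusted p = 0.00362, 0.00479, 0.00461 and 0.00618. Of 12388 genes tested, 101 were higher and 144 lower with BPTES. Of these, 94 and 136 differed by 2-fold or more. All 245 had 3 BPTES libraries on one side of the 3 aging libraries, as did 24.0% of all tested genes, where chance gives 10%. An unadjusted p under 0.05 was reached by 1822 genes. Aging replicate 1 lay apart from the rest: without it 816 genes were higher and 841 lower, among them all 101 and all 144 in the same direction. Without aging replicate 2 the count of changed genes was 51, without aging replicate 3 it was 54, and without BPTES replicates 1, 2 and 3 it was 116, 29 and 31. Of 63 genes named by the rule that passed, all 63 kept the call without aging replicate 1, 21 and 22 without aging replicates 2 and 3, and 36, 12 and 13 without BPTES replicates 1, 2 and 3. Of 56 tested genes named by the rule that did not pass, 36 passed without aging replicate 1.

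**Figure D1:**
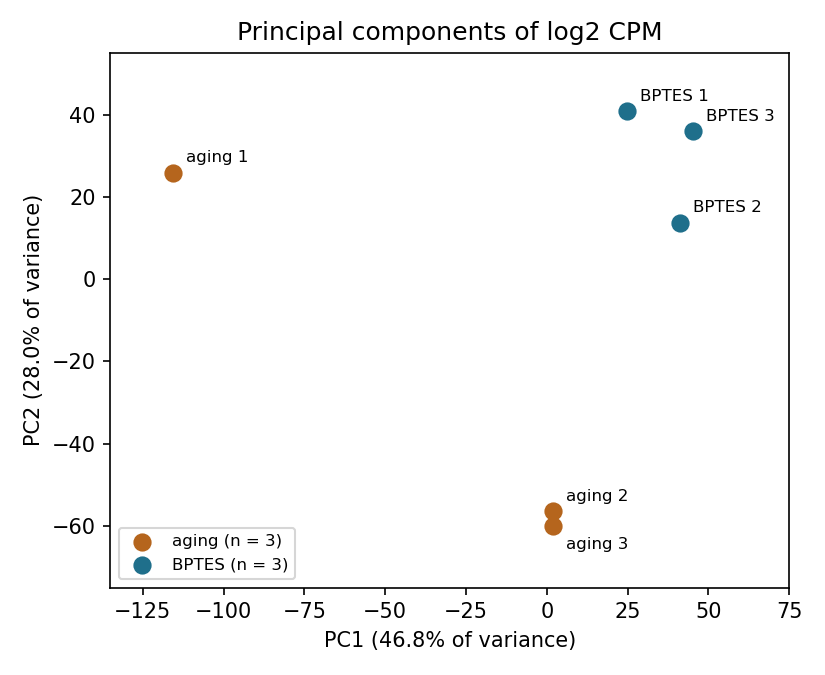
Principal components of log2 CPM over the 12388 tested genes, one point per library, coloured by group (n = 3 each). Aging replicate 1 lies at -116 on PC1, which holds 46.8% of the variance, while aging replicates 2 and 3 lie at 1.96 and 1.98 and the BPTES libraries between 24.9 and 45.4.

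The largest increases included male-biased genes. Hsd3b5, a ketosteroid reductase of male liver (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252 in mm10), rose from 3.66 ± 1.67 to 275 ± 2.63 CPM (SD, n = 3 each), a log2 fold change of 6.24 ± 0.38 (SE, adjusted p = 6.21e-04). Mup15, one of the genes for major urinary proteins (ENSMUSG00000096674, chromosome 4, 61435790 to 61439743), rose from 26.3 ± 1.26 to 1099.7 ± 102 CPM (log2 fold change 5.38 ± 0.18, adjusted p = 4.09e-05). Slco1a1, an uptake carrier for organic anions (ENSMUSG00000041698, chromosome 6, 141907282 to 141946962), rose from 34.5 ± 3.75 to 813 ± 83.2 CPM (log2 fold change 4.56 ± 0.20, adjusted p = 1.34e-04). Elovl3, a fatty acid elongase (ENSMUSG00000038754, chromosome 19, 46131897 to 46135694), rose from 42.5 ± 12.7 to 928 ± 63.8 CPM (adjusted p = 6.21e-04). Cyp4a12a, a fatty acid hydroxylase, rose by a log2 fold change of 4.59 ± 0.38 (adjusted p = 0.00251). Mup11, Mup13 and Mup17 rose by log2 fold changes of 5.21, 4.53 and 4.47. Cml5, now named Nat8f5, rose from 0.286 ± 0.439 to 15.1 ± 3.61 CPM (adjusted p = 0.0403). Ces2b, a carboxylesterase, held 2 reads over the aging group and 118 over the BPTES group, a ratio, scaled for library size, of 76.1 (95% interval 20.6 to 636) that covers counting error only (adjusted p = 0.0371). Of 20 Mup genes tested, 17 rose; their sequences are nearly identical, so the reads of single members are uncertain.

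The largest decreases included genes of inflammation and female-biased genes. Ccl8, a chemokine for monocytes (ENSMUSG00000009185, chromosome 11, 82115185 to 82116799), held 220 reads over the aging group and 1 over the BPTES group, a ratio of 171 (95% interval 30.3 to 6765) (adjusted p = 0.0415). Ngp, a protein of neutrophil granules, held 267 and 2 reads, a ratio of 103 (95% interval 28.4 to 859) (adjusted p = 0.0283). Hhipl2 held 243 and 3 reads, a ratio of 62.8 (95% interval 21.2 to 307) (adjusted p = 0.0258). Chi3l1, a chitinase-like protein now named Chil1, fell from 6.44 ± 3.41 to 0.09997 ± 0.101 CPM (log2 fold change -6.15 ± 0.77, adjusted p = 0.0128). Bmper, which binds bone morphogenetic proteins, fell from 21.2 ± 1.69 to 0.878 ± 1.05 CPM (adjusted p = 0.0344). Sult3a1, a sulfotransferase, fell from 13.3 ± 3.08 to 0.440 ± 0.621 CPM (adjusted p = 0.0453), and Cux2, a transcription factor of female liver, fell from 13.8 ± 2.95 to 0.667 ± 0.596 CPM (adjusted p = 0.0453). Cyp2b13, a female-biased cytochrome P450, fell from 4.19 ± 0.983 to 0.124 ± 0.143 CPM (adjusted p = 0.0233).

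**Figure D2:**
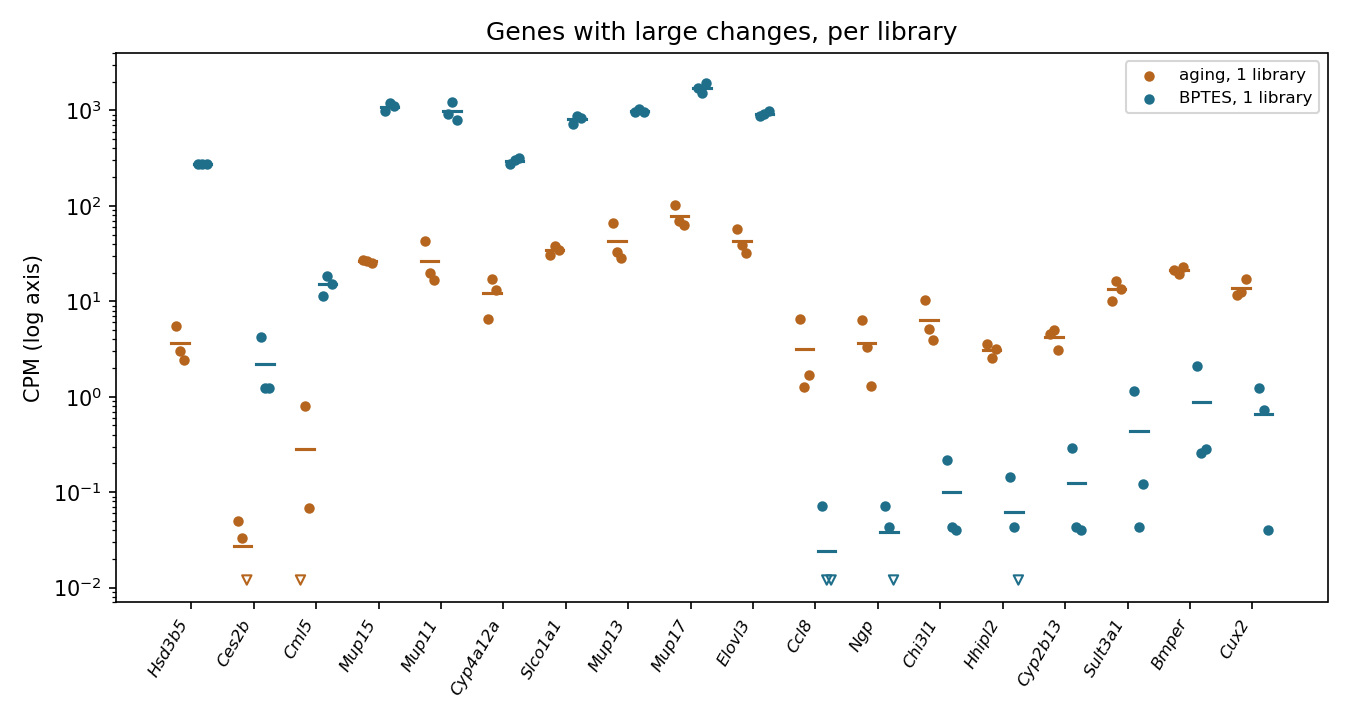
CPM (log axis) of the 10 genes with the largest positive and 8 of the 10 with the largest negative log2 fold change among genes past the threshold with a mean of at least 1 CPM, predicted gene models left out, one point per library and a bar at each group's mean (n = 3 each); open triangles mark libraries without a read. Hsd3b5 lies at 3.66 CPM on average in the aging group and at 275 CPM in the BPTES group, and Cux2 at 13.8 and 0.667 CPM.

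Of 45 gene lists fixed before the data were examined, 40 had at least 5 tested genes and 25 passed the threshold (camera with a preset correlation of 0.01, Benjamini-Hochberg adjusted p under 0.05), 11 of them upward and 14 downward. With a correlation estimated for each list 7 passed, namely the male-biased, endoplasmic reticulum stress, heat shock, monocyte-derived macrophage, M2, microbial sensing and cell cycle lists. Some lists that lost the call had an estimated correlation below the preset 0.01 (-0.0643 to 0.00325). They were the tricarboxylic acid cycle, fatty acid oxidation, glucose, M1, stellate cell, urea cycle, interferon and periportal lists. A larger correlation between genes does not account for the loss of those calls. Even for the endoplasmic reticulum stress list, with an estimated correlation of -0.0346, the adjusted camera p rose from 1.04e-18 to 0.0116. A call lost with an estimated correlation, here and below, therefore does not by itself show that the genes of a list move together. Without aging replicate 1 the count at the preset correlation was 26, and 23 lists passed in the same direction with and without that library. With both that library left out and the correlation estimated, 3 passed, namely the male-biased, endoplasmic reticulum stress and heat shock lists (adjusted p = 0.0419 each), and the other 4 of the 7 lost the call, namely the monocyte-derived macrophage (adjusted p = 0.0977), M2 (0.126), microbial sensing (0.0873) and cell cycle (0.162) lists. With an estimated correlation 0 and 0 lists passed without aging replicates 2 and 3, and 5, 0 and 2 without BPTES replicates 1, 2 and 3. Fewer libraries were tested there, so a lost call does not show that it depended on a single library. Without aging replicates 2 and 3 and BPTES replicate 2 the male-biased list did not pass (camera adjusted p = 0.0514, 0.0611 and 0.0528). Its median was 2.03, 2.39 and 2.05 there, against 2.01 with no library left out.

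**Figure D3:**
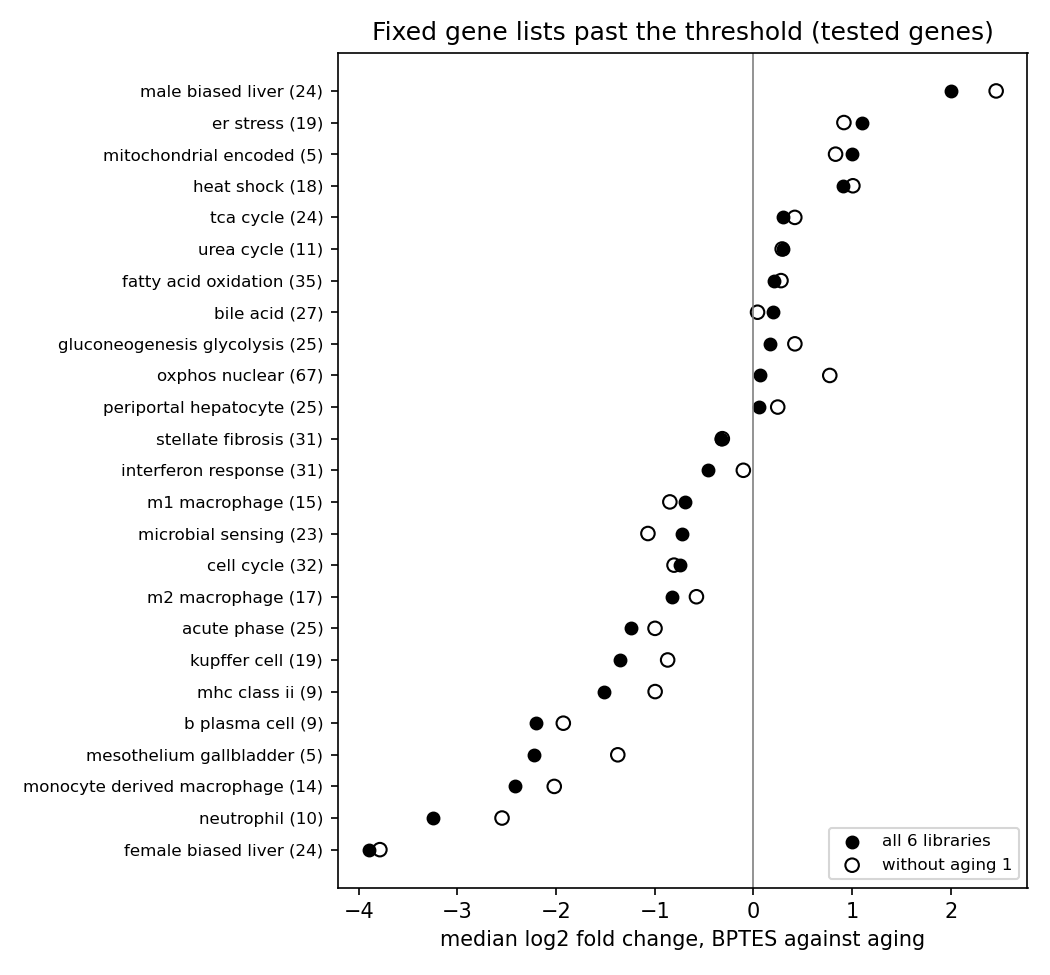
Median log2 fold change of the 25 lists past the threshold, with the number of tested genes in parentheses, over all 6 libraries (filled) and without aging replicate 1 (open). The medians run from -3.89 for female-biased genes to 2.01 for male-biased genes, and that of nuclear oxidative phosphorylation genes moves from 0.07 to 0.77.

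The male-biased list passed upward and the female-biased list downward. Of 24 male-biased genes 19 rose, 22 adjusted over the list alone, with a median log2 fold change of 2.01 (camera adjusted p = 9.66e-38). Mup7, at 571 ± 13.9 CPM in the aging group, reached 11679 ± 1321 CPM (SD, n = 3; adjusted p = 4.09e-05), and Mup1 rose by a log2 fold change of 4.34 ± 0.22 (adjusted p = 3.37e-04). Cyp4a12b, the neighbour of Cyp4a12a and close to it in sequence, rose from 4.90 ± 0.472 to 73.6 ± 3.81 CPM (adjusted p = 3.37e-04). Without its Mup genes the list kept 17 tested members, of which 14 rose, with a median of 2.05. Of 24 female-biased genes 6 fell, 20 adjusted over the list alone, and all 24 had negative fold changes, with a median of -3.89 (camera adjusted p = 5.51e-20; adjusted p = 0.0612 with an estimated correlation). Cyp17a1, a steroid hydroxylase, fell from 94.4 ± 20.4 to 12.5 ± 3.13 CPM (log2 fold change -2.92 ± 0.28, adjusted p = 0.00394). Atp6v0d2, a subunit of the vacuolar proton pump, fell from 40.4 ± 12.2 to 4.31 ± 2.43 CPM (adjusted p = 0.0193), and Cyp2c69 fell from 39.2 ± 7.26 to 10.8 ± 0.780 CPM (adjusted p = 0.0106). Past the threshold without aging replicate 1 were 22 male-biased genes higher and 20 female-biased genes lower.

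Chaperone genes rose in 2 lists. Of 19 genes of the unfolded protein response 6 rose, 18 adjusted over the list alone, and all 19 had positive fold changes, with a median log2 fold change of 1.10 (camera adjusted p = 1.04e-18). Herpud1, of the degradation pathway of the endoplasmic reticulum, rose from 155 ± 2.48 to 523 ± 49.5 CPM (adjusted p = 0.00352). Hspa5, the chaperone BiP (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), rose from 767 ± 11.8 to 1933 ± 141 CPM (log2 fold change 1.33 ± 0.14, adjusted p = 0.00627). Hyou1, another chaperone of that compartment, rose from 114 ± 33.0 to 422 ± 40.1 CPM, and Syvn1, a ubiquitin ligase there, rose from 51.2 ± 3.89 to 153 ± 12.2 CPM (adjusted p = 0.0155 and 0.00851). Of 18 heat shock genes 5 rose, 11 adjusted over the list alone, with a median of 0.91 (camera adjusted p = 5.00e-12). Hspa1b, an inducible Hsp70 with a near-identical paralog, rose from 13.7 ± 1.504 to 36.7 ± 3.83 CPM (adjusted p = 0.0193), and Hsph1 rose from 54.7 ± 18.8 to 192 ± 11.3 CPM (adjusted p = 0.0284). Chordc1 and Dnaja1 rose by log2 fold changes of 1.201 and 1.03; the fifth, Stip1, named after its value was seen, rose by 1.11. Of the first list 18 passed upward without aging replicate 1, and of the second 16.

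The acute-phase list of hepatocytes passed downward. Of 25 tested 9 fell, 19 adjusted over the list alone, with a median log2 fold change of -1.24 (camera adjusted p = 1.48e-16; adjusted p = 0.102 with an estimated correlation). The fibrinogen chains Fgb and Fgg fell from 15770.1 ± 106 to 7853 ± 368 CPM and from 12108 ± 204 to 6251 ± 208 CPM (SD, n = 3; adjusted p = 0.00728 and 0.00921). Apcs, serum amyloid P, fell from 885 ± 285 to 141 ± 44.8 CPM (log2 fold change -2.65 ± 0.32, adjusted p = 0.0106). Itih3, an inhibitor chain of the inter-alpha-trypsin family, fell from 3851 ± 64.8 to 1699 ± 185 CPM (adjusted p = 0.00964). The list stood higher in aging replicate 1 than in aging replicates 2 and 3, by a median log2 ratio of 0.99; without that library its median fold change was -0.997. There 17 of its genes passed downward.

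The lists of resident and of blood-derived macrophages passed downward. Of 19 Kupffer cell genes 5 fell, 14 adjusted over the list alone, with a median log2 fold change of -1.35 (camera adjusted p = 4.89e-11; adjusted p = 0.0537 with an estimated correlation) and of -0.87 without aging replicate 1, where the list stood higher by a median log2 ratio of 0.88 than in aging replicates 2 and 3. Vsig4, a complement receptor, fell from 94.0 ± 14.6 to 32.7 ± 3.19 CPM (log2 fold change -1.52 ± 0.20, adjusted p = 0.0152). Emr1, the F4/80 antigen now named Adgre1 (ENSMUSG00000004730, chromosome 17, 57358691 to 57483527), fell from 27.3 ± 4.89 to 10.6 ± 1.94 CPM (adjusted p = 0.0419), a call that held without aging replicate 1 and was lost without each of the other libraries (adjusted p 0.151 to 0.238, and 4.85e-05 to 0.238 over 16 alternatives). Spic, a transcription factor of macrophages, fell from 7.83 ± 0.779 to 2.20 ± 0.451 CPM, Ctsc, cathepsin C, fell from 261 ± 48.2 to 119 ± 11.4 CPM, and Lyz2, lysozyme, named after its value was seen, fell from 187 ± 61.7 to 62.7 ± 14.9 CPM. Clec4f, a lectin of Kupffer cells (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187), lay at 204 ± 92.7 and 89.5 ± 17.2 CPM and did not pass (adjusted p = 0.137; 1.43e-06 to 0.429 over 16 alternatives, and 0.0222 without aging replicate 1). Of 14 genes of monocytes and monocyte-derived macrophages 4 fell, 11 adjusted over the list alone, with a median of -2.42 (camera adjusted p = 2.82e-11). These were Itgam, an integrin of myeloid cells, which fell from 9.92 ± 0.587 to 1.71 ± 0.408 CPM (adjusted p = 0.0126), Cd14, a receptor for bacterial lipopolysaccharide, which fell from 31.0 ± 13.7 to 3.57 ± 1.22 CPM (adjusted p = 0.0146), Spp1, osteopontin, which fell from 187 ± 9.05 to 85.5 ± 5.52 CPM (adjusted p = 0.0203), and Cx3cr1, the fractalkine receptor, which fell from 4.05 ± 1.56 to 0.383 ± 0.230 CPM (adjusted p = 0.0483). Past the threshold without aging replicate 1 were 13 Kupffer cell and 11 monocyte-derived genes, all lower.

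The neutrophil, B cell, antigen presentation and microbial sensing lists passed downward. Of 10 neutrophil genes 3 fell, 8 adjusted over the list alone, with a median log2 fold change of -3.25 (camera adjusted p = 1.35e-09; adjusted p = 0.0881 with an estimated correlation). S100a9, a calcium-binding protein of neutrophils, fell from 13.9 ± 6.61 to 1.57 ± 0.469 CPM (adjusted p = 0.0191), and Lcn2, which hepatocytes also make in the acute phase, fell from 1137 ± 566 to 112 ± 71.9 CPM (adjusted p = 0.0304); the third was Ngp. The median was the same with 1 member that had no read in a group set to its bound. S100a8 had a log2 fold change of -2.52 ± 0.55 (adjusted p = 0.0738) and passed without aging replicate 1. Of 9 genes of B and plasma cells 2 fell, 4 adjusted over the list alone, with a median of -2.20 (camera adjusted p = 9.32e-07; adjusted p = 0.0618 with an estimated correlation): Igj, the immunoglobulin joining chain now named Jchain, fell from 19.7 ± 2.30 to 3.45 ± 1.02 CPM (adjusted p = 0.00951), and Ighg2c, an immunoglobulin heavy chain, fell from 28.1 ± 9.11 to 3.42 ± 2.74 CPM (adjusted p = 0.0471). Sdc1 had a log2 fold change of -0.72 and passed only without aging replicate 1 among the libraries left out in turn. Of 9 genes of MHC class II presentation 1 fell, 5 adjusted over the list alone, with a median of -1.52 (camera adjusted p = 4.59e-05; adjusted p = 0.144 with an estimated correlation). The one was Ctss, cathepsin S, which fell from 102 ± 11.6 to 43.2 ± 4.52 CPM (adjusted p = 0.0248). The class II chains H2-Aa, H2-Ab1 and H2-DMb1 had log2 fold changes of -1.52, -1.63 and -2.59 and did not pass, but each did without aging replicate 1. Over 16 alternatives these fold changes ran from -1.71 to -0.996, -1.94 to -0.86 and -2.91 to -1.77. Without aging replicate 1 the MHC class II median was -0.996; relative to aging replicates 2 and 3 that library stood higher by a median log2 ratio of 1.47 on this list and 1.26 on the neutrophil list. Of 23 receptors and effectors for bacterial products 5 fell, 9 adjusted over the list alone, with a median of -0.72 (camera adjusted p = 5.09e-06). They were Cd14 and Lcn2, the inflammatory caspase Casp4, the inhibitor of Toll-like receptor signalling Irak3, and Nfkbiz, with log2 fold changes of -2.10, -2.72 and -1.32 for the last 3. Lower past the threshold without aging replicate 1 were 6 neutrophil, 3 B cell, 4 MHC class II and 8 microbial sensing genes.

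The lists of M2 and of M1 macrophage markers both passed downward. Of 17 M2 genes 1 fell, 5 adjusted over the list alone, with a median log2 fold change of -0.83 (camera adjusted p = 3.25e-06). The one was Il1rn, the interleukin-1 receptor antagonist, which fell from 19.4 ± 1.93 to 5.14 ± 1.04 CPM (adjusted p = 0.0155). The classical M2 markers did not pass: Mrc1, the mannose receptor (ENSMUSG00000026712, chromosome 2, 14229392 to 14332057), had a log2 fold change of -0.32 ± 0.24 (adjusted p = 0.639; 4.79e-04 to 0.901 over 16 alternatives), Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527) one of 0.09 ± 0.30 (adjusted p = 0.938), and Arg1, which hepatocytes express highly (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484), one of 0.01 ± 0.13 (adjusted p = 0.987). Mrc1 passed without aging replicate 1, at -0.50 (adjusted p = 0.0457). Msr1, Chi3l3 and Irf4 had log2 fold changes of -1.44, -3.09 and -3.32 and did not pass either, but each did without aging replicate 1. Of 15 M1 genes 0 passed by edgeR's quasi-likelihood test over all genes, 6 fell adjusted over the list alone, and the median was -0.69 (camera adjusted p = 0.00154; adjusted p = 0.0618 with an estimated correlation) and -0.42 without aging replicate 3. Passing an unadjusted p of 0.05 were 0 higher and 6 lower; with DESeq2 0 higher and 6 lower passed, and with limma-voom 0 higher and 0 lower. Fcgr1, Ccl5, Cd86 and Socs3 had log2 fold changes of -1.63, -3.61, -1.59 and -1.05, and Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139) one of -1.16 ± 0.29 (adjusted p = 0.0994); these 5 did not pass over all 6 libraries and passed without aging replicate 1, where 5 M2 and 7 M1 genes were lower past the threshold. Nos2, Tnf and Il6 lay under the count filter, with 5, 59 and 27 reads over the aging group and 10, 4 and 8 over the BPTES group. The M2 minus M1 score averaged 0.25 ± 0.18 in the aging libraries and -0.25 ± 0.18 in the BPTES libraries (log2 units, SD, n = 3 each), a difference of -0.50 with an exact permutation p of 0.1, two-sided, the smallest that 3 against 3 allows. Recomputed with the count filter applied anew, the difference was 0.01 without aging replicate 1 and 0.05 without BPTES replicate 1. Other genes entered these scores: without aging replicate 1, 18 M2 genes (Arg1 included) and 17 M1 genes were tested. These values therefore do not show that a single library carried the difference. Over the 16 and 15 genes the score was 0.46, 0.16 and 0.13 in aging replicates 1, 2 and 3. It was -0.30, -0.39 and -0.05 in BPTES replicates 1, 2 and 3.

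The list of glutamine genes did not pass. Of 32 enzymes and carriers of glutamine and glutamate 0 passed by edgeR's quasi-likelihood test over all genes, 2 did adjusted over the list alone, and the median log2 fold change was 0.00, within -0.02 to 0.05 with 1 library left out (camera adjusted p = 0.605). The 2 were Got1, an aspartate aminotransferase, at -0.94 ± 0.18 (adjusted p = 0.0512), and Gclc, of glutathione synthesis, at 1.17 ± 0.26 (adjusted p = 0.0751), both named after their values were seen. An unadjusted p under 0.05 was reached by 4 higher and 3 lower, with DESeq2 1 higher and 2 lower passed, and with limma-voom 0 higher and 1 lower. Without aging replicate 1, 6 list members rose and 5 fell, Gclc and Got1 among them. Gls2, the liver-type glutaminase (ENSMUSG00000044005, chromosome 10, 128194457 to 128210004), lay at 271 ± 14.2 and 263 ± 9.49 CPM (SD, n = 3 each; log2 fold change -0.04 ± 0.15, adjusted p = 0.943), and Glul, glutamine synthetase (ENSMUSG00000026473, chromosome 1, 153899944 to 153909723), at 991 ± 81.0 and 1015 ± 15.7 CPM (0.03 ± 0.14, adjusted p = 0.950).

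The lists of glucose, bile acid, fatty acid oxidation and tricarboxylic acid cycle genes passed upward with camera's preset correlation, and none of the 4 did with an estimated one. The estimated correlation was 0.0466 for bile acids. For the glucose, fatty acid oxidation and tricarboxylic acid cycle lists it lay below the preset 0.01 (0.00325, -0.0190 and -0.0226). Of 25 genes of gluconeogenesis and glycolysis 2 rose, 9 adjusted over the list alone, with a median log2 fold change of 0.16 (camera adjusted p = 0.00133; adjusted p = 0.0618 with an estimated correlation). They were Pfkfb1 and Pfkfb3, which set the level of fructose 2,6-bisphosphate, with log2 fold changes of 0.996 ± 0.18 and 1.52 ± 0.29; G6pc and Pygl, at 0.68 and 0.60, passed only without aging replicate 1 among the libraries left out in turn. The median was 0.42 without aging replicate 1, 0.33 without aging replicate 3 and 0.36 without BPTES replicate 3. Of 27 bile acid genes 3 rose, 3 adjusted over the list alone, where 1 also fell, with a median of 0.20 (camera adjusted p = 0.00320; adjusted p = 0.136 with an estimated correlation) and of 0.04, 0.32 and 0.31 without aging replicates 1, 2 and 3. They were Slco1a1, Cyp8b1, the sterol hydroxylase of cholic acid synthesis, which rose from 105 ± 23.9 to 310.3 ± 30.8 CPM (adjusted p = 0.0169), and Cyp7b1, a male-biased oxysterol hydroxylase, which rose from 129 ± 11.4 to 319 ± 30.8 CPM (adjusted p = 0.0146). Slco1a4 had a log2 fold change of -1.13 (adjusted p = 0.0914) and passed without aging replicate 1. Of 35 genes of fatty acid oxidation 2 rose, which were Cyp4a12a and Cyp4a12b and are also male-biased; adjusted over the list alone 3 rose and 2 fell, and the median was 0.21 (camera adjusted p = 0.0250; adjusted p = 0.103 with an estimated correlation) and 0.13 without BPTES replicate 1. Acot1 and Acot3, thioesterases, had log2 fold changes of 1.58 and -1.53 and did not pass, but both did without aging replicate 1. Of 24 genes of the tricarboxylic acid cycle 0 passed by edgeR's quasi-likelihood test, over all genes or adjusted over the list alone, 21 had positive fold changes, and the median was 0.30 (camera adjusted p = 2.09e-04; adjusted p = 0.0537 with an estimated correlation). Aco1, Sdha and Cs had log2 fold changes of 0.64, 0.47 and 0.43 and did not pass, but each did without aging replicate 1. Passing an unadjusted p of 0.05 were 4 higher and 0 lower; with DESeq2 3 higher and 0 lower passed, and with limma-voom 0 higher and 0 lower. The genes past the threshold without aging replicate 1 numbered 12 higher for glucose, 10 higher and 3 lower for bile acids, 16 higher and 8 lower for fatty acid oxidation and 14 higher for the tricarboxylic acid cycle.

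In 5 further lists the call was lost when single libraries were left out. Of 25 periportal hepatocyte genes 2 rose and 1 fell, 5 and 2 adjusted over the list alone. Etnppl and Cyp2f2 rose by log2 fold changes of 1.46 and 1.07, and Ctsc, also a Kupffer cell marker, fell. The median was 0.06 (camera adjusted p = 0.0250; adjusted p = 0.107 with an estimated correlation). Without aging replicates 1, 2 and 3 and BPTES replicate 1 it was 0.25, 0.13, 0.10 and 0.10, and the call was lost without aging replicates 2 and 3 (adjusted p = 0.0516 and 0.0980; 3.31e-04 to 0.139 over all alternatives). Of 11 urea cycle genes 0 passed by edgeR's quasi-likelihood test, 0 adjusted over the list alone, with a median of 0.29 (camera adjusted p = 0.0250; adjusted p = 0.118 with an estimated correlation). An unadjusted p under 0.05 was reached by 3 higher and 0 lower, with DESeq2 1 higher and 0 lower passed, and with limma-voom 0 higher and 0 lower. The call was lost without aging replicates 2 and 3 (adjusted p = 0.0649 and 0.0951; 4.24e-05 to 0.118 over all alternatives). Slc25a13, Otc, Glud1 and Ass1 had log2 fold changes of 0.52, 0.43, 0.40 and 0.27, and each passed without aging replicate 1. Of 31 interferon response genes 0 passed by edgeR's quasi-likelihood test, 0 adjusted over the list alone, with a median of -0.46 (camera adjusted p = 0.0328; adjusted p = 0.113 with an estimated correlation). Passing an unadjusted p of 0.05 were 1 higher and 5 lower; with DESeq2 0 higher and 2 lower passed, and with limma-voom 0 higher and 0 lower. The call was lost without aging replicates 1 and 2 and BPTES replicates 2 and 3 (adjusted p = 0.0708, 0.0628, 0.0603 and 0.0645; 0.00930 to 0.113 over all alternatives). The median was -0.10 without aging replicate 1 and -0.31 without BPTES replicate 3. Zbp1, Oasl2, Igtp and Irf7 had log2 fold changes of -1.32, -0.75, -0.63 and -0.77, and Igtp passed without aging replicate 1. The genes past the threshold without aging replicate 1 numbered 10 higher and 2 lower for periportal hepatocytes, 5 higher for the urea cycle and 5 lower for the interferon response.

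The calls for genes of the respiratory chain depended on single libraries. Of 67 nuclear genes of oxidative phosphorylation 0 passed by edgeR's quasi-likelihood test, 0 adjusted over the list alone, with a median log2 fold change of 0.07 (camera adjusted p = 0.0190; adjusted p = 0.791 with an estimated correlation). An unadjusted p under 0.05 was reached by 2 higher and 1 lower, with DESeq2 0 higher and 0 lower passed, and with limma-voom 0 higher and 0 lower. Aging replicate 1 stood above aging replicates 2 and 3 on this list by a median log2 ratio of 1.67, and without it 36 members rose, with a median of 0.77. Without aging replicates 2 and 3 and BPTES replicates 1, 2 and 3 the median was -0.16, -0.20, -0.18, 0.22 and 0.12. The call was lost without the first 3 of these (adjusted p = 0.917, 0.879 and 0.246; 2.61e-23 to 0.917 over all alternatives). Cycs, Uqcrc2 and Atp5a1 had log2 fold changes of 0.53, 0.44 and 0.28, and each passed without aging replicate 1. Of 5 mitochondrially encoded genes tested, 0 passed by edgeR's quasi-likelihood test and 1 did, upward, adjusted over the list alone, mt-Nd4 with a log2 fold change of 0.80; mt-Nd5, mt-Co3 and mt-Nd4l had 0.84, 1.43 and 1.34, and mt-Nd4 passed without aging replicate 1. Passing an unadjusted p of 0.05 were 1 higher and 0 lower; with DESeq2 1 higher and 0 lower passed, and with limma-voom 0 higher and 0 lower. The median was 1.002 (camera adjusted p = 0.0421; adjusted p = 0.351 with an estimated correlation). It was -0.0106 without BPTES replicate 1 and 1.51 without BPTES replicate 2. The call was lost without aging replicates 1 and 2 and BPTES replicate 1 (adjusted p = 0.0721, 0.0649 and 0.371; 0.00420 to 0.466 over all alternatives). Fry, which tests whether the genes of a list move one way on balance, gave adjusted p = 0.733 for the nuclear and 0.234 for the mitochondrially encoded genes, and under 0.05 for the other 23 lists past the threshold.

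The stellate cell, cell cycle and mesothelial lists passed downward, with few or none of their genes past the threshold. Of 31 genes of stellate cells and fibrosis 1 fell, 1 adjusted over the list alone, with a median log2 fold change of -0.33 (camera adjusted p = 0.00259; adjusted p = 0.0618 with an estimated correlation). It was Col5a2, a chain of type V collagen (ENSMUSG00000026042, chromosome 1, 45374321 to 45503282), which fell from 49.0 ± 8.40 to 6.21 ± 1.44 CPM (log2 fold change -2.98 ± 0.27, adjusted p = 0.00340); Ctgf, now Ccn2, Vim and Col6a1 had log2 fold changes of -0.79, -0.92 and -0.92 and did not pass, though Ctgf did without aging replicate 1. Of 32 cell cycle genes 1 fell, 1 adjusted over the list alone, and 28 had negative fold changes, with a median of -0.74 (camera adjusted p = 4.59e-05). It was Mki67, a marker of dividing cells, which fell from 11.4 ± 2.88 to 2.68 ± 0.921 CPM (adjusted p = 0.0390); Top2a, Mcm5 and Prc1 had log2 fold changes of -1.46, -1.78 and -1.97 and did not pass, though Top2a and Prc1 did without aging replicate 1. Over 15 alternatives the median of the cell cycle list ran from -0.96 to -0.32, and it passed in 14 (highest camera adjusted p = 0.0816). Of 5 tested genes of mesothelium and gallbladder 0 passed by edgeR's quasi-likelihood test and 1 did, downward, adjusted over the list alone, Msln, with 132 reads over the aging group and 3 over the BPTES group (adjusted p = 0.106). An unadjusted p under 0.05 was reached by 0 higher and 4 lower, with DESeq2 0 higher and 1 lower passed, and with limma-voom 0 higher and 0 lower. Wt1, Upk3b and Krt8 had log2 fold changes of -2.22, -2.27 and -0.64, which ran from -2.69 to -1.87, -3.12 to -1.05 and -0.78 to -0.25 over the alternatives. The median of that list was -2.22 (camera adjusted p = 0.00188; adjusted p = 0.0782 with an estimated correlation), and -1.37 without aging replicate 1. Lower past the threshold without that library were 2 stellate cell, 3 cell cycle and 0 mesothelial genes.

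Gene length moved with the distance of aging replicate 1 from its group. Across 12327 genes, the log2 ratio of that library to aging replicates 2 and 3 had a Spearman correlation of -0.491 with gene length, against -0.105, 0.187 and -0.0307 for BPTES replicates 1, 2 and 3 against the others of their group. Genes are not independent replicates, so these values describe the libraries. Pearson's r of log2 CPM across genes was 0.879 and 0.876 between aging replicate 1 and aging replicates 2 and 3, and 0.977 between the latter. The squared difference in counts between aging replicates 2 and 3, averaged over genes, was still 9.40 times the sampling variance. The short transcripts of cytosolic ribosomal proteins stood higher in aging replicate 1 by a median log2 ratio of 1.78; as a list of 74 genes, 0 of which passed by edgeR's quasi-likelihood test, DESeq2 or limma-voom over all genes, adjusted over the list alone or at an unadjusted p under 0.05, they had a median fold change of -0.38 (camera adjusted p = 0.163) and of 0.42 without that library. Without aging replicates 2 and 3 and BPTES replicates 1, 2 and 3 it was -0.61, -0.64, -0.70, -0.21 and -0.26.

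**Figure D4:**
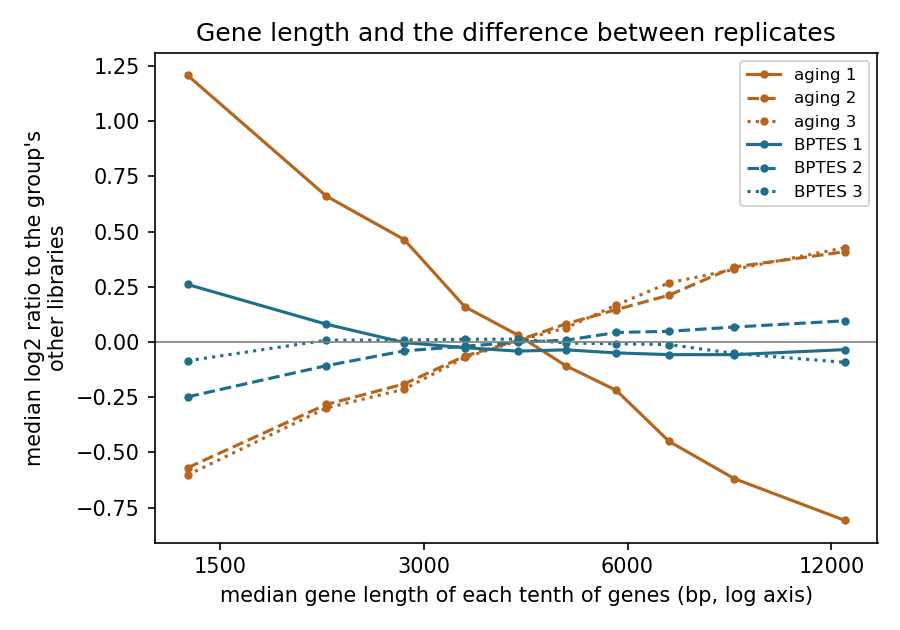
Median log2 ratio of each library to the other libraries of its group (vertical axis) in 10 equal parts of the genes ordered by length, at the median gene length of each part in bp (log axis). Aging replicate 1 falls from 1.21 in the part with the shortest genes to -0.81 in that with the longest, while aging replicates 2 and 3 mirror it because it is among the libraries they are compared with.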

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

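The tests with library weights, with the length trend removed, with robust hyperparameters, without both replicates numbered 1 and with both an estimated correlation and 1 library left out were chosen after the data were seen. The count of 245 changed genes stayed within 1.5 times of its value with DESeq2's size factors, no filter, the filter at 5 CPM, limma-voom, robust hyperparameters and a fold threshold. It became 538 (179 higher, 359 lower) at an adjusted p under 0.1, 981 (324 higher, 657 lower) with the DESeq2 Wald test, 2768 (1329 higher, 1439 lower) with a weight per library, where aging replicate 1 received 0.0901, 463 (224 higher, 239 lower) with the length trend removed and 3130 (1615 higher, 1515 lower) without both replicates numbered 1. With 1 library left out it ran from 29 to 1657, 24 to 816 of them higher and 5 to 841 lower; fewer samples were tested there, and the rise without aging replicate 1 came with a fall of the biological coefficient of variation from 0.388 to 0.256. Of the 63 genes named by the rule and past the threshold, 63 stayed past it without aging replicate 1, 21 and 22 without aging replicates 2 and 3, and 36, 12 and 13 without BPTES replicates 1, 2 and 3. None of the 63 changed sign under any alternative run, but their groups did not overlap, so leaving out 1 library could hardly change a sign. With the replicate number as a block (replicate block) 234 genes changed, 102 higher and 132 lower, and 26 lists passed; deviations from the group means of same-numbered libraries correlated by 0.212, 0.148 and 0.0346, aging replicate 3 correlated better with BPTES replicate 2 (0.154), and the numbers were not taken to pair the samples. The count of 25 lists became 7 with an estimated correlation, and 0 to 5 with that and 1 library left out; it was 18 to 28 in the alternatives with the preset correlation. The difference in the M2 minus M1 score ran from -0.70 to 0.0492 with 1 library left out. The count filter was applied anew there, so other genes entered the score and the range is not the effect of the libraries alone. Fold changes of 8 genes that did not pass over all 6 libraries changed sign, and the cause was not tested: with 1 library left out Gls2 ran from -0.0776 to 9.64e-04, Glul -0.0284 to 0.0817, Cd163 -0.11 to 0.35, Arg1 -0.00887 to 0.0604, Hbb-bs -1.51 to 0.0655, mt-Co3 -0.0799 to 2.13 and mt-Nd4l -0.0106 to 1.999. With the filter at 5 CPM Glul was -0.0311 and Arg1 -0.0576; with library weights Glul was -0.025, Cd163 -0.0187 and mt-Nd4l -0.12; with the length trend removed Gls2 was 0.0905; without both replicates numbered 1 Glul was -0.0199, mt-Nd5 -0.0159 and mt-Nd4l -0.51, and Hbb-bs, at -0.35, passed there and in no other alternative.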

Other observations

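The tests of the KEGG pathways, of Ddx3y, of the Mup genes, of the endothelial against the Kupffer cell list, of hemoglobin without aging replicate 1 and without both replicates numbered 1 and of the spread left after removal of the length trend were chosen after the results they bear on were seen. Genes of fat synthesis moved in both directions. Lpin1, a phosphatidate phosphatase, rose from 113 ± 5.01 to 436 ± 23.1 CPM (adjusted p = 0.00251), Fasn, fatty acid synthase, rose from 319 ± 30.5 to 688 ± 30.1 CPM (adjusted p = 0.0181), and Me1, malic enzyme, rose from 186 ± 30.7 to 428 ± 43.0 CPM (adjusted p = 0.0288), while Cd36, a fatty acid carrier, fell from 113 ± 39.7 to 28.5 ± 8.32 CPM (SD, n = 3 each; adjusted p = 0.0390). Of 32 tested genes of that list 3 rose and 1 fell, 8 and 5 adjusted over the list alone, with a median log2 fold change of -0.02 (-0.09 to 0.02 with 1 library left out), while its camera direction was up (adjusted p = 0.281). Among genes of drug metabolism Cyp1a2 rose from 196 ± 25.2 to 488 ± 24.2 CPM (adjusted p = 0.0142), Ephx1, Ces2c and Cyp3a11 rose by log2 fold changes of 1.03, 2.01 and 0.98, and Cyp2b13 fell. Car3, a carbonic anhydrase, rose from 529.9 ± 97.8 to 3013 ± 92.5 CPM (adjusted p = 0.00134), and Alas2, the erythroid enzyme of heme synthesis, rose from 27.3 ± 3.33 to 106 ± 4.96 CPM (adjusted p = 0.00406). Ccrn4l, a clock output now named Noct, fell from 183 ± 16.4 to 34.2 ± 11.1 CPM (adjusted p = 0.00842), 1 of 20 tested clock genes. Dusp1, an immediate early gene, rose by a log2 fold change of 1.008. These genes were named after their values were seen; of 14 such genes past the threshold, all 14 kept the call without aging replicate 1, 4 and 4 without aging replicates 2 and 3, and 4, 2 and 3 without BPTES replicates 1, 2 and 3.

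The other lists did not pass. For each list the second median below is without the library aging replicate 1. The range in parentheses is that of the medians with 1 of the 6 libraries left out in turn. The count filter was applied anew there, so a list can hold other members and its full median can lie outside the range. Of the intestinal genes, for example, 3 were tested over all 6 libraries and 4 without aging replicate 1. Senescence genes, among which Ccl8 fell, had 0 higher and 2 lower of 20 genes, 1 and 3 adjusted over the list alone, median -0.45, -0.23 without the library (-0.54 to -0.23), camera adjusted p = 0.0953. Drug metabolism had 4 higher and 1 lower of 41 genes, 8 and 16 adjusted over the list alone, median -0.36, -0.41 without the library (-0.41 to -0.09), camera adjusted p = 0.163. Bile duct cell genes, of which Spp1 fell, had 0 higher and 1 lower of 13 genes, 0 and 2 adjusted over the list alone, median -0.38, -0.59 without the library (-0.61 to -0.03), camera adjusted p = 0.191. T and NK cell genes had 0 higher and 0 lower of 10 genes, 0 and 1 adjusted over the list alone, median -1.32, -0.59 without the library (-1.33 to -0.59), camera adjusted p = 0.199. Cholesterol synthesis had 0 higher and 0 lower of 23 genes, 1 and 0 adjusted over the list alone, median 0.06, 0.08 without the library (0.02 to 0.11), camera adjusted p = 0.238, and immediate early genes had 1 higher and 0 lower of 19 genes, 2 and 4 adjusted over the list alone, median -0.10, 0.19 without the library (-0.35 to 0.19), camera adjusted p = 0.387. In 6 lists, beside that of fat synthesis given above, the median or mean and the camera direction differed in sign. Red blood cell genes had 1 higher and 0 lower of 6 genes, 1 and 0 adjusted over the list alone, median -0.76, 0.68 without the library (-1.49 to 0.68), camera adjusted p = 0.577, with camera upward. NRF2 targets, of which Ephx1 and Me1 rose, had 2 higher and 0 lower of 24 genes, 4 and 4 adjusted over the list alone, median -0.07, 0.21 without the library (-0.14 to 0.21), camera adjusted p = 0.671, with camera upward. ATF4 targets had 0 higher and 0 lower of 27 genes, 0 and 0 adjusted over the list alone, median -0.05, 0.37 without the library (-0.27 to 0.37), camera adjusted p = 0.746, with camera upward. Clock genes had 0 higher and 1 lower of 20 genes, 0 and 1 adjusted over the list alone, median 0.04, -0.13 without the library (-0.13 to 0.11), camera adjusted p = 0.893, with camera downward. Endothelial genes had 0 higher and 0 lower of 21 genes, 0 and 0 adjusted over the list alone, median -0.06, 0.11 without the library (-0.12 to 0.11), camera adjusted p = 0.898, with camera upward. Pericentral hepatocyte genes, of which Cyp1a2 rose, had 1 higher and 0 lower of 24 genes, 3 and 2 adjusted over the list alone, median 0.03, 0.07 without the library (-0.15 to 0.07), camera adjusted p = 0.671, with a mean of -0.0523 and camera upward. Without aging replicate 1 the NRF2, ATF4 and ribosomal protein lists passed upward at the preset correlation only (camera adjusted p = 0.0245, 0.0261 and 4.44e-06; adjusted p = 0.162, 0.309 and 0.516 with an estimated correlation). The ribosomal protein list passed the other way, downward, without aging replicates 2 and 3 and BPTES replicate 1 (camera adjusted p = 1.77e-04, 1.59e-04 and 0.00194; adjusted p = 0.676, 0.689 and 0.732 with an estimated correlation). The genes past the threshold without aging replicate 1 numbered 7 higher and 18 lower for drug metabolism, 10 and 8 for fat synthesis, 7 and 6 for pericentral hepatocytes, 6 and 2 for NRF2 targets and 4 and 0 for ATF4 targets. Of the lists too short for camera, 4 of 9 adipose, 3 of 14 intestinal, 1 of 16 muscle, 1 of 25 pancreatic and 4 of 6 sex chromosome genes were above the filter, of which Car3 rose, with list medians of -1.70, -1.03, -1.73, 1.09 and 0.16, of -1.04, 0.12, -1.43, 2.07 and 0.05 without aging replicate 1, and within -1.94 to -1.04, -0.96 to 0.12, -2.18 to -1.43, 0.11 to 2.07 and 0.05 to 0.26 with 1 library left out, where the muscle gene was under the filter without aging replicate 2. Of 276 KEGG pathways in the authors' gene annotation, 54 passed, 47 of these also without aging replicate 1 and 0 with an estimated correlation. Among them protein processing in the endoplasmic reticulum had a median of 0.26 (camera adjusted p = 4.27e-08; adjusted p = 0.160 with an estimated correlation), primary bile acid biosynthesis one of 0.44 (camera adjusted p = 1.96e-04; adjusted p = 0.198 with an estimated correlation), tryptophan metabolism one of 0.31 (camera adjusted p = 1.10e-05; adjusted p = 0.198 with an estimated correlation) and cytokine receptor interaction one of -0.43 (camera adjusted p = 1.04e-04; adjusted p = 0.198 with an estimated correlation).

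Aging replicate 1 lay apart from aging replicates 2 and 3. A label swapped between the groups would place aging replicate 1 nearer to BPTES. Positions were taken over 1619 genes that differ between BPTES and aging replicates 2 and 3, from 0 (aging) to 1 (BPTES). The median position of aging replicate 1 was 0.394, which argues against a swap. It was 0.515 over genes higher and 0.309 over genes lower with BPTES, so the higher genes alone do not argue against one. The bootstrap 95% interval of the median over all 1619 genes was 0.325 to 0.467. Genes are not independent replicates, so that interval does not measure the spread between libraries. A length-dependent difference between libraries may account for part of the distance of aging replicate 1, with a Spearman correlation of -0.491, but not for the whole. With the length trend removed, the log2 ratio of that library to its group still had an SD over genes of 1.17. The largest such SD of a BPTES library was 0.732. A stronger acute-phase state of that animal stays open too. The median log2 ratio of the acute-phase list was 0.988. Over 10000 lists matched on expression and length the median was 0.450 and the central 95% ended at 0.866. Those lists were drawn gene by gene, while the acute-phase list had an estimated correlation of 0.402, so that range can be too narrow. The shift was not particular to this list. It was 2.13 for red blood cell, 1.78 for ribosomal protein, 1.67 for nuclear oxidative phosphorylation, 1.47 for MHC class II, 1.26 for neutrophil and 1.06 for T and NK cell genes. A length-dependent difference and an acute-phase state can hold together, and no biological group of the design separates this library. BPTES replicate 1 also lay further from its group than the others. The squared difference of its counts from those of BPTES replicates 2 and 3, averaged over genes, was 76.1 and 74.5 times the sampling variance. Between the latter this value was 12.5, and between aging replicate 1 and aging replicates 2 and 3 it was 345 and 349.

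The male-biased list passed upward with BPTES and the female-biased list downward. In camera the latter passed with the preset correlation but not with an estimated one (adjusted p = 0.0612), while fry gave it adjusted p = 0.00362. Animals of different sex are argued against by Ddx3y, whose lowest value over the 6 libraries was 112 CPM. Reads shared between near-identical Mup genes do not carry the pattern, since the male-biased list without them had a median log2 fold change of 2.05, and the single library aging replicate 1 does not either, since without it the larger adjusted camera p of both lists was 2.76e-13 at the preset correlation, though with an estimated correlation the male-biased list passed (adjusted p = 0.0419) and the female-biased list did not (adjusted p = 0.126). A candidate explanation is a difference between the animals in the hormonal control of sex-dependent liver genes, with BPTES or with another feature of the groups such as illness; no hormone was measured, and this stays an untested hypothesis found on the same data.

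The Kupffer cell, monocyte-derived macrophage, neutrophil and acute-phase lists passed downward with BPTES at camera's preset correlation. With an estimated correlation the second passed and the other lists did not (camera adjusted p = 0.0537, 0.0881 and 0.102). Fry gave those adjusted p = 0.00479, 0.00461 and 0.00618. A lower share of hepatocytes in the aging libraries would raise other cell types alike, but the endothelial median lay above the Kupffer cell median by 1.29 on the log2 scale (-0.06 and -1.35; permutation of genes, p = 0.0001, the smallest that 10000 permutations give). Genes are not independent replicates, so that p does not measure the spread between libraries. With 1 library left out the endothelial median ran from -0.12 to 0.11 and the Kupffer cell median from -1.38 to -0.87. The single library aging replicate 1 does not carry the fall of the 4 lists at the preset correlation, since without that library their largest adjusted camera p was 4.33e-05. With an estimated correlation the Kupffer cell, monocyte-derived macrophage, neutrophil and acute-phase lists did not pass without it (camera adjusted p = 0.126, 0.0977, 0.1003 and 0.168). More blood could add to the fall of these lists in aging replicate 1, where Hbb-bs lay at 322 CPM against 69.5 and 63.4 CPM in aging replicates 2 and 3 and with which the hemoglobin genes had a median log2 fold change of -1.09. In aging replicates 2 and 3 some extra blood stays open, as the hemoglobin median was 0.45 without aging replicate 1 but -0.38 without both replicates numbered 1, where Hbb-bs passed at -0.35 (adjusted p = 0.0248; 0.0248 to 0.908 over 16 alternatives), yet its lower 95% bound, -0.57, lay above the Kupffer cell, monocyte-derived macrophage and neutrophil medians there (-1.02, -2.36 and -2.67), so blood is argued against as the whole; an effect of BPTES on these cells, or inflammation in the aging animals for another reason, stays open and untested.

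The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 245 changed genes and the highest of the others 0; it gave 25 lists and the highest of the others 16, so in each case 1 of the 10 splits, the real one, gave as many.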
